A study of Mus musculus with 2 samples.

How the data were processed

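Single-cell suspensions of mouse embryos were measured as 2 pooled libraries, 1 in vivo (embryonic day 4.5) and 1 ex vivo (24 h of culture). The embryos were dissociated with Accumax and glass capillaries, and dispersed single cells were picked by hand before loading on the Chromium instrument. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger (8.0.0 per the processing notes, 8.0.1 per the matrix header) on mm10. The annotation release is not given in the sources used here. The matrices had 32286 features, of which 32285 were Ensembl genes and 1 was a reporter sequence, gtdTomato. Gene positions were taken from GENCODE vM21, in which 32235 of the identifiers were found. Of the 999 genes on the fixed lists, 993 were found by symbol. Where several identifiers shared a symbol (40 cases), the symbol went to the one with the most UMIs.

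The deposited matrices were the starting point, and no reads were aligned again. A barcode was kept as a cell with at least 1000 genes and at most 15% mitochondrial UMIs. In the in vivo library 126 barcodes were left out, 115 with too few genes, 89 with too many mitochondrial UMIs and 78 with both, holding 2.30% of the UMIs. In the ex vivo library 87 were left out (82, 69 and 64), holding 1.53% of the UMIs. Barcodes left out had median mitochondrial shares of 79.4% and 81.8%, against 2.57% and 2.22% in kept cells. Kept cells ranged from 2081 to 176115 UMIs in vivo and from 1888 to 244487 ex vivo, and their sums were 11565534 and 10631683 UMIs. No cell was removed as a doublet. With 1 library per group the depth sets only the counting error, so the spread between embryos or preparations is unknown.

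Cells of both libraries were clustered together without integration, with scanpy 1.11.5, igraph 0.11.9 and Python 3.11.15. Counts were scaled to 10000 per cell and log-transformed, and the 2000 most variable genes were z-scored (clipped at 10) for 20 principal components, 15 neighbours and Leiden clusters at resolution 0.5 (seed 1). A cluster took the type with the largest share of its fixed markers at least 2-fold higher than in the other cells and with a UMI in at least 25% of the cluster's cells. At least 3 such markers were needed, and no other type could have more markers among the cluster's top 10 genes. A much shallower cluster (median depth under that of its libraries divided by 3) would stay unnamed without own markers among those 10. A finer clustering at resolution 1.0 was used to describe cells within classes.

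For each class and library, UMIs were summed over cells and divided by the sum to give CPM. The log2 ratio of ex vivo over in vivo used a pseudocount of 10 CPM, whereas folds given for single genes are plain CPM ratios. Counts of list members at least 1.5-fold higher or lower follow the ratio with the pseudocount, so weakly expressed members with a larger plain fold are not counted. Intervals at 95% were exact: Poisson for a sum, conditional binomial for a ratio and Clopper-Pearson for a share, while a share of 0 is given with a limit of 3 counts of the total (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3). For 49 fixed lists (37 gene lists and 12 marker sets), the median log2 ratio was taken over members with at least 20 UMIs in both sums together, if at least 3 were measured. It was compared with 10000 random lists drawn from the same 10 bins of expression. A list was called above or below when its median lay in the outer 2.5% on that side. A percentile among random lists compares genes within 1 pair of libraries and is no test between groups. Figures were drawn with matplotlib 3.10.9.

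Genes named in the text are, per class, the 12 with the largest log2 ratio in each direction among genes with at least 50 UMIs in the library where CPM is higher and a UMI in at least 25% of that library's cells. Mitochondrially encoded genes, ribosomal protein genes and unnamed gene models were left out of that ranking. Members of the fixed lists are named as examples of their list, by rule the 4 measured members with the largest absolute log2 ratio. Their folds are therefore extremes of the list and not typical of it. A class's own markers could be named as well. The filters, marker and gene lists, resolution, pseudocount, naming rule and most alternatives were fixed before the data were examined. After the data were seen, 3 choices were made: shared symbols go to the identifier with the most UMIs, the top 10 check counts the markers of subtypes with those of their parent type, and marker-score classes use only the 3 embryonic lineages.

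The alternatives were a looser filter (200 genes, no mitochondrial limit), a stricter filter (2000 genes, 10%), resolutions 0.25 and 1.0, classes from each cell's highest marker score, and removal of doublets called by Scrublet (expected rate 0.05, 2 in vivo cells and 1 ex vivo cell). Others were scaling by the median of ratios, totals without mitochondrial and ribosomal genes, the mean of per-cell CPM, a pseudocount of 1 CPM, and members with at least 100 UMIs or at least 1 UMI. Cells were also thinned to 13000 UMIs each, which left out 12 in vivo and 17 ex vivo cells. A setting with deeper cells only (at least 30000 UMIs and at most 4% mitochondrial UMIs) was added after the data were seen.

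The calculation was tested on simulated data with 50 genes changed at each of 4 folds in sums drawn from the epiblast-like means. Simulated folds of 2, 4, 0.5 and 0.25 came back as medians of 1.90, 3.70, 0.54 and 0.36, since the pseudocount draws ratios toward 1. The 95% intervals covered the simulated fold for 96%, 94%, 98% and 94% of these genes. The sums were drawn from the Poisson model that the intervals assume, and variation between cells was left out. This coverage therefore checks the calculation only and does not show how the intervals hold in real cells. A list of genes all raised 4-fold reached percentile 100 and a list of unchanged genes percentile 30.4.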

Results

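The data are UMI counts of single cells from mouse embryos of the hybrid strain B6D2F1/J, measured with droplet-based 3' sequencing (10x Genomics Chromium). Embryos isolated at embryonic day 4.5 (33 embryos from 4 mice) made up the in vivo library, and embryos kept in culture for 24 h (32 embryos from 4 donor mice) made up the ex vivo library. The labels give embryonic day 4.5 for both libraries. They do not state whether this is the day before or after culture, so a difference in stage cannot be told apart from culture. Each group has 1 pooled library and therefore no replicates. Library preparation and group cannot be told apart, no test between groups was possible, and every interval below is an exact 95% interval that covers counting error only. The in vivo library held 11837729 UMIs in 273 barcodes and the ex vivo library 10797149 UMIs in 249 barcodes. Of these barcodes, 147 and 162 were kept as cells, with medians of 81315 and 62864 UMIs and of 7375 and 7094 genes per cell. The comparison asks how the cell classes of the peri-implantation embryo differ in expression between in vivo embryos and embryos after culture.

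Every kept cell fell into 1 of 3 classes named from fixed marker lists: epiblast-like, primitive endoderm-like and trophectoderm-like. Epiblast-like cells made up 51.7% (43.3 to 60.0%, exact Clopper-Pearson) of the in vivo cells and 25.3% (18.8 to 32.7%) of the ex vivo cells. The primitive endoderm-like share was 29.9% (22.7 to 38.0%) in vivo and 32.7% (25.6 to 40.5%) ex vivo. Trophectoderm-like cells were 18.4% (12.5 to 25.6%) of the in vivo and 42.0% (34.3 to 49.97%) of the ex vivo cells. Among epiblast-like and primitive endoderm-like cells together, the primitive endoderm-like share was 36.7% (28.1 to 46.0%) in vivo and 56.4% (45.8 to 66.6%) ex vivo. Dispersed cells were picked by hand after dissociation, so these shares describe the cells picked and not the make-up of the embryos.

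**Figure D1:**
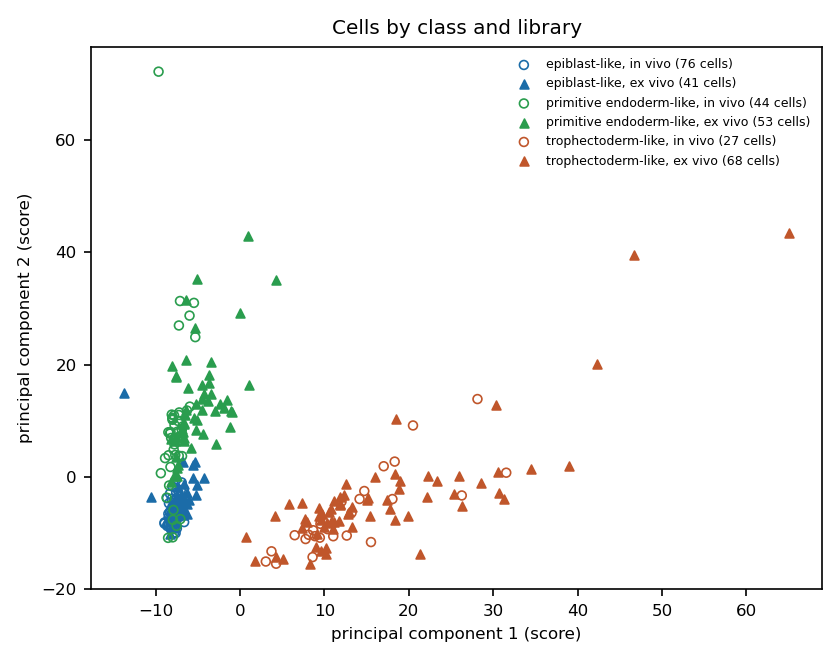
Scores of the 309 kept cells on principal components 1 and 2 (no unit), with colour for the class, open circles for in vivo and filled triangles for ex vivo cells. Trophectoderm-like cells mostly lie at higher scores on component 1, and some primitive endoderm-like and epiblast-like cells overlap on these components.

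**Figure D2:**
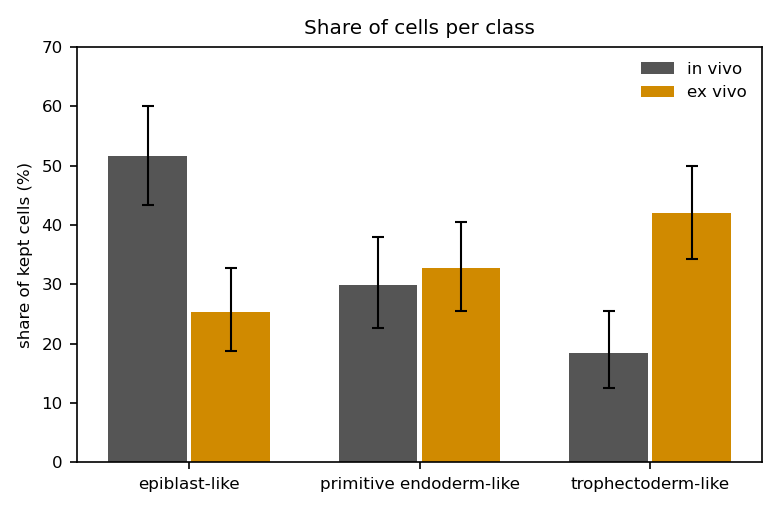
Share of kept cells (%) in each class for the in vivo and the ex vivo library, where bars are shares and whiskers exact 95% binomial intervals. Epiblast-like cells were 51.7% in vivo and 25.3% ex vivo, and trophectoderm-like cells 18.4% and 42.0%.

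The UMIs of each class were summed per library and scaled to 1000000 (CPM). Fixed gene lists are described by their median log2 ratio of ex vivo over in vivo and by the number of measured members whose ratio, with the pseudocount of 10 CPM, was at least 1.5-fold higher or lower. Folds given for single genes are plain CPM ratios without a pseudocount. The range given with a list holds the central 95% of the medians of 10000 random lists matched on expression. Over all measured genes the median log2 ratio was 0.04 in epiblast-like, 0.14 in primitive endoderm-like and 0.04 in trophectoderm-like cells. A fold against a count of 0 is a lower bound, computed with 3 counts over the class sum.

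In all 3 classes, genes of the amino acid and integrated stress response, p53 targets and targets of the oxidative stress factor NRF2 lay above their random range. The list of metallothionein and metal response genes and the trophoblast adhesion genes lay above their random range as well. DNA replication, cholesterol biosynthesis, glycolysis and heat shock genes lay below it in all 3 classes. These are 5 and 4 of the 46 lists measured in each class, which were not all the same lists. Lists above and below numbered 13 and 5 in epiblast-like, 19 and 11 in primitive endoderm-like and 12 and 10 in trophectoderm-like cells. Lying outside the range was thus common, and a call alone does not single out a list. Some genes are on more than 1 list, so calls for different lists are not independent. Slc7a11 is on the integrated stress response and NRF2 lists, and Sesn2 on the integrated stress response and p53 lists. Hmox1, Fth1 and Ftl1 are on the NRF2 and metal response lists, and Klf4 on the naive pluripotency and immediate early lists. Sparc, Nid1, Lama1, Lamb1, Col4a1, Col4a2 and Serpinh1 are on both the parietal endoderm and basement membrane lists. Visceral endoderm markers and transport genes share Ttr, Apoc2, Amn, Cubn, Lrp2 and others. Trophectoderm markers share keratin genes and Cldn4 with the epithelial list, and Krt7, Lgals3 and others with the mural markers. At least 1 alternative setting ended the call for adhesion genes in each class, for heat shock genes in primitive endoderm-like and trophectoderm-like cells, and for NRF2 targets in primitive endoderm-like cells. The same held for the integrated stress response in primitive endoderm-like, p53 targets in epiblast-like and glycolysis in trophectoderm-like cells.

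Epiblast-like cells had higher stress response genes and lower glycolysis and cholesterol genes ex vivo, while the pluripotency lists stayed inside their random ranges. Nupr1, a chromatin-associated stress gene induced by the factor ATF4, had 12.5 CPM in vivo and 434 CPM ex vivo, 34.7-fold higher (27.9 to 43.8). The lactate dehydrogenase gene Ldha was 2.29-fold lower ex vivo (2.14 to 2.45), at 845 CPM in vivo and 369 CPM ex vivo. Upp1, a uridine phosphorylase gene of the early epiblast, was 3.90-fold lower (329 and 84.3 CPM, 3.41 to 4.48). On mm10, Nupr1 lies on chromosome 7 (126623249 to 126630861), Ldha on chromosome 7 (46841475 to 46855627) and Upp1 on chromosome 11 (9118103 to 9136170).

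The amino acid and integrated stress response list had the highest median in this class, 1.02 (range -0.13 to 0.14), with 18 of 24 measured members higher and 0 lower. Among them, the transcription factor gene Cebpb was 12.2-fold higher (8.41 to 18.2) and the serine synthesis gene Psph 4.64-fold (3.98 to 5.41). Trib3, a pseudokinase gene that acts back on ATF4, was 4.43-fold higher (3.51 to 5.62). The mitochondrial carboxykinase gene Pck2, not on the list but chosen by the naming rule, was 6.50-fold higher (4.82 to 8.85). Of the p53 targets, 9 of 20 were higher and 0 lower (median 0.42, range -0.11 to 0.20), including the cell cycle inhibitor Cdkn1a, 5.34-fold (3.83 to 7.54), and Phlda3, 4.10-fold (3.02 to 5.61). With cells thinned to equal depth, the p53 median was 0.26 and inside its range. NRF2 targets had 9 of 23 members higher (median 0.34, range -0.17 to 0.10), such as the cystine transporter gene Slc7a11, 9.97-fold (5.22 to 20.6), and Gclm of glutathione synthesis, 2.64-fold (2.27 to 3.08). Lysosome genes (median 0.21, 4 of 27 higher) and metallothionein and metal response genes (0.47, 3 of 9 higher) also lay above their ranges. So did interferon response (0.20) and imprinted genes (0.21). Both of these were inside as means of per-cell CPM, with medians of 0.19 and 0.23 and wider random ranges.

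Glycolysis genes were lower ex vivo in 9 of 21 members and higher in 0 (median -0.42, range -0.18 to 0.10). Besides Ldha these included the aldolase gene Aldoa, 2.33-fold lower (2.19 to 2.49), Tpi1, 2.47-fold lower (2.18 to 2.82), and the lactate exporter gene Slc16a3, 3.102-fold lower (2.54 to 3.81). Hypoxia genes had 7 of 22 members lower and 4 higher (median -0.26, range -0.09 to 0.19), with Ankrd37 5.45-fold lower (3.11 to 10.4) and Ddit4 3.58-fold higher (2.55 to 5.06). Cholesterol biosynthesis was lower in 9 of 24 members (median -0.32, range -0.10 to 0.17), including its rate-limiting gene Hmgcr, 2.47-fold (1.93 to 3.19), and Dhcr7, 5.62-fold (2.62 to 14.3). Of the heat shock and chaperone genes, 6 of 19 were lower and 1 higher (median -0.46, range -0.19 to 0.10). Hsph1 was 1.91-fold lower (1.71 to 2.14) and the mitochondrial chaperonin gene Hspd1 1.69-fold (1.61 to 1.76).

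The naive pluripotency list (median 0.01, range -0.18 to 0.10), the formative and primed list (0.07, range -0.12 to 0.15) and the epiblast markers (-0.12, range -0.19 to 0.05) were inside their ranges. Single members differed, with Nanog, a factor of naive pluripotency, 1.90-fold higher (1.61 to 2.25) and the threonine dehydrogenase gene Tdh 1.86-fold lower (1.71 to 2.02). Lef1, a WNT effector gene, was 3.61-fold lower ex vivo (3.14 to 4.17), and Tcf15, a factor gene linked to priming, 3.397-fold (2.80 to 4.15). Ace was 9.59-fold lower (5.12 to 20.3) and Hopx 4.88-fold (3.15 to 7.92). Further genes chosen by the naming rule were Arrdc4, 11.4-fold higher (8.35 to 15.9), the calcitonin gene Calca, 11.9-fold (8.39 to 17.2), Ubap1l, Usp26, Glipr2, Hist1h2ap and Reep5. On the lower side they were Zfp428, Trem2, Eno1b, Ripk3, Osbpl7 and Aire. Hist1h2ap and Eno1b have close copies in the genome, so the split of their reads is uncertain. Osbpl7 had 60.5% of its in vivo UMIs in 1 cell and a log2 ratio of -1.42, which was -0.71 as a mean of per-cell CPM. In thinned cells Ripk3 moved from -1.49 to -0.84 and Aire from -1.41 to -0.61. Primitive endoderm markers (median 0.56), visceral (0.46) and parietal endoderm markers (0.32) lay above their ranges in this class, but inside them with the looser cell filter and with marker-score classes, and 1 ex vivo cell held 81.8% of the Lama1 UMIs.

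**Figure D3:**
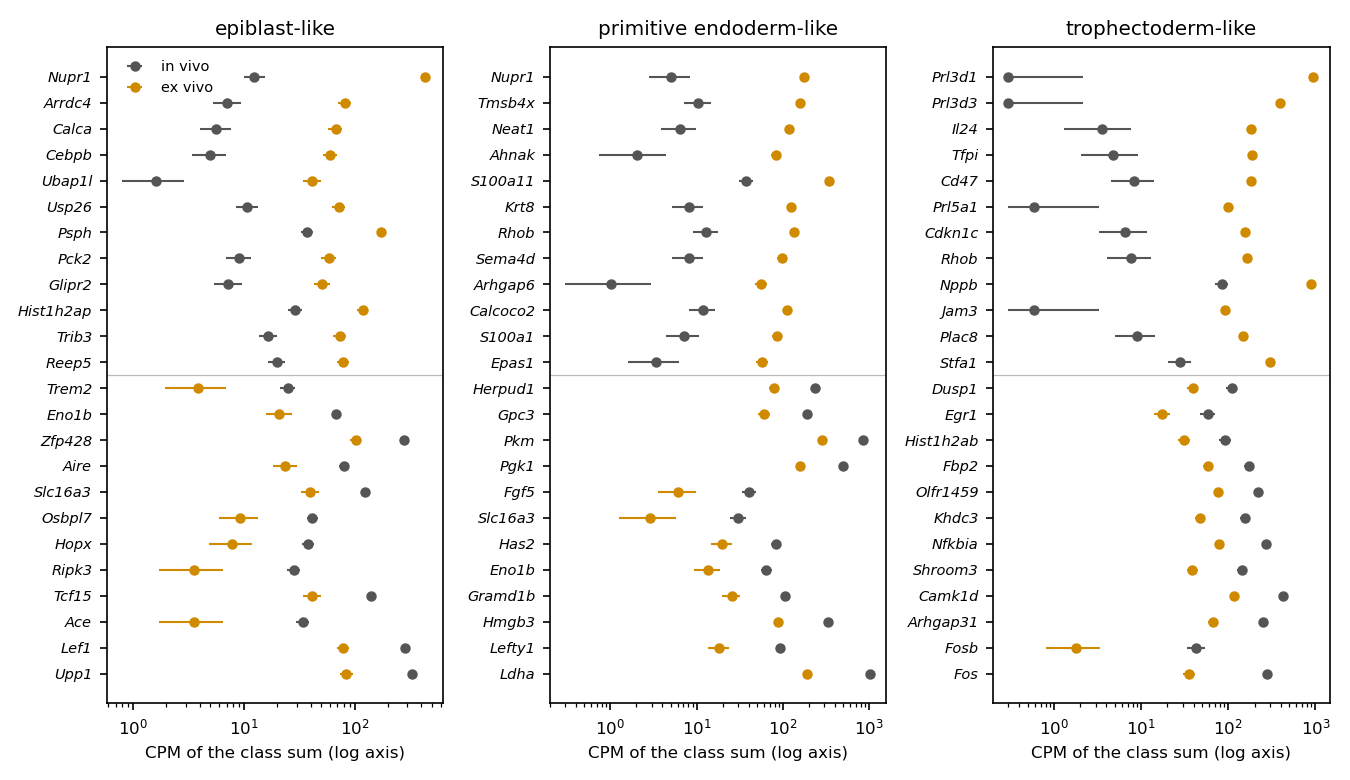
CPM of the class sum (log axis) in vivo and ex vivo for the 12 genes with the largest ratio in each direction per class, higher ex vivo above the line and lower below it. Bars are exact 95% Poisson intervals and values of 0 are drawn at the left end of the axis: Prl3d1 had 0 UMIs in vivo and 942 CPM ex vivo in trophectoderm-like cells.

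Primitive endoderm-like cells of the ex vivo library had lower visceral endoderm, unfolded protein response and glycolysis genes than those of the in vivo library, and higher epithelial, actin and p53 target genes. Cited1, a transcriptional co-regulator gene of visceral endoderm, was 2.74-fold lower (494 and 180 CPM, 2.47 to 3.04). The endoplasmic reticulum chaperone gene Hspa5 was 2.70-fold lower (2445 and 905 CPM, 2.58 to 2.83), and Ldha 5.37-fold (1012 and 189 CPM, 4.89 to 5.90). The epithelial keratin gene Krt8 was 15.2-fold higher (8.04 and 123 CPM, 10.1 to 24.1) and Nupr1 34.5-fold (5.03 and 173 CPM, 20.7 to 62.1). On mm10, Cited1 lies on chromosome X (102247381 to 102252181), Hspa5 on chromosome 2 (34771970 to 34777547) and Krt8 on chromosome 15 (101996698 to 102004482).

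Visceral endoderm markers were lower in 8 of 15 members and higher in 3 (median -0.65, range -0.17 to 0.35). Lefty1, a NODAL antagonist gene of the anterior visceral endoderm, was 5.15-fold lower (3.80 to 7.11), the homeobox gene Hhex 3.15-fold (2.45 to 4.08) and the endocytic receptor gene Lrp2 1.92-fold (1.82 to 2.03). Apoc2, an apolipoprotein gene of the same list, was 2.45-fold higher (1.89 to 3.19). Visceral endoderm transport genes had 5 of 12 members lower and 3 higher (median -0.35, range -0.22 to 0.32). Parietal endoderm markers were higher in 7 of 16 and lower in 0 (median 0.47, range -0.23 to 0.23), among them Cryab, 5.52-fold (3.99 to 7.77), and Snai1, 2.91-fold (1.72 to 5.14). Basement membrane genes were higher in 7 of 20 (median 0.39, range -0.21 to 0.21), with the collagen-modifying enzyme gene Plod1 4.88-fold (3.02 to 8.25), Nid1 2.28-fold (1.68 to 3.12) and the perlecan gene Hspg2 1.69-fold (1.52 to 1.89). At a finer clustering, 29 in vivo cells and 1 ex vivo cell of this class formed a cluster led by Cited1, Amn and Ttr. Another, led by Bmper, Lama1 and Pth1r, held 9 in vivo and 45 ex vivo cells, so the class sums compare different finer clusters, and a cluster mostly of 1 library may be that library rather than a cell type.

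The unfolded protein response list had 14 of 20 members lower and 0 higher (median -0.92, range -0.25 to 0.14). Herpud1, a gene of protein degradation at the endoplasmic reticulum, was 3.05-fold lower (2.61 to 3.56), Creld2 2.63-fold (2.35 to 2.96) and Sdf2l1 2.53-fold (2.25 to 2.85). Glycolysis genes were lower in 9 of 20 and higher in 1 (median -0.44, range -0.18 to 0.23), such as Pgk1, 3.15-fold (2.83 to 3.51), Pkm, 3.01-fold (2.78 to 3.27), and Slc16a3, 10.4-fold (5.07 to 24.9). Ribosome biogenesis genes (median -0.32, range -0.18 to 0.19) included the polyamine gene Srm, 2.16-fold lower (1.97 to 2.37). Mitosis genes were lower in 6 of 30 and higher in 1 (median -0.25, range -0.16 to 0.20), with Aurka 1.93-fold lower (1.63 to 2.30) and Cdk1 1.81-fold (1.59 to 2.06). Cholesterol biosynthesis had 6 of 24 members lower and 2 higher (median -0.16, range -0.15 to 0.26), among them Ebp, 2.20-fold (1.93 to 2.53). Formative genes were lower in 5 of 16 and higher in 2 (median -0.20, range -0.07 to 0.37), led by the growth factor gene Fgf5, 6.54-fold (3.92 to 11.6).

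Actin and mechanosensing genes were higher in 14 of 25 members and lower in 0 (median 0.81, range -0.12 to 0.28). The calponin gene Cnn2 was 10.0-fold higher (5.36 to 20.7), and Amotl2, a regulator of YAP at cell junctions, 3.12-fold (2.39 to 4.12). Tight junction and epithelial genes were higher in 12 of 23 and lower in 1 (median 0.61, range -0.07 to 0.34), with Krt18 4.09-fold (3.18 to 5.30) and the E-cadherin gene Cdh1 2.66-fold (2.14 to 3.33). Immediate early genes were higher in 11 of 18 (median 0.74, range -0.04 to 0.38), including Klf6, 3.38-fold (2.92 to 3.93), and Jun, 2.59-fold (2.04 to 3.31). Of the p53 targets, 13 of 20 were higher (median 0.85, range -0.04 to 0.37), such as the pro-apoptotic gene Pmaip1, 6.10-fold (3.77 to 10.4), and the cyclin gene Ccng1, 4.04-fold (2.85 to 5.82). The amino acid and integrated stress response had 10 of 23 members higher and 1 lower (median 0.45, range -0.10 to 0.32), with Atf5 5.98-fold (3.98 to 9.29) and the asparagine synthetase gene Asns 2.29-fold (1.98 to 2.64). In thinned cells this median was 0.30 and inside its range. The PI3K list was higher in 8 of 23 (median 0.47, range -0.05 to 0.35), led by the translation repressor gene Eif4ebp1, 3.39-fold (3.03 to 3.80). Lysosome genes were higher in 10 of 27 (median 0.39, range -0.15 to 0.23), including Psap, 3.49-fold (2.70 to 4.56), and Grn, 4.69-fold (3.04 to 7.49).

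Trophectoderm markers (7 of 13 higher, median 0.90, range -0.14 to 0.39) and mural trophectoderm markers (7 of 11 higher, median 0.83, range -0.19 to 0.38) also lay above their ranges in primitive endoderm-like cells. Naive pluripotency genes were higher in 5 of 14 (median 0.43, range -0.15 to 0.36), with Klf2 8.85-fold (5.16 to 16.3) and Klf4 2.43-fold (1.98 to 2.99). At least 1 alternative ended the calls for naive pluripotency, formative, trophectoderm marker and visceral endoderm transport genes in this class. Other genes chosen by the naming rule were the nuclear RNA Neat1, 18.5-fold higher (11.6 to 31.1), the scaffold gene Ahnak, 40.8-fold (18.5 to 112), S100a11, 9.10-fold (7.47 to 11.2), and Tmsb4x, Rhob, Calcoco2, S100a1, Epas1, Arhgap6 and Sema4d. Arhgap6 had 3 UMIs in vivo and 153 ex vivo, a 55.1-fold ratio (18.5 to 269.9), and 92.6% of the ex vivo Sema4d UMIs came from 1 cell. On the lower side were the chromatin gene Hmgb3, 3.73-fold (3.24 to 4.31), the hyaluronan synthase gene Has2, 4.22-fold (3.13 to 5.78), Gramd1b, Eno1b and Gpc3. Gpc3 had a log2 ratio of -1.53 from the class sum and -2.22 as a mean of per-cell CPM. In thinned cells Nupr1 was at 4.28 against 3.61, Sema4d at 3.19 against 2.57 and Fgf5 at -2.29 against -1.64. Median depth in this class was 72332.5 UMIs per cell in vivo and 46927 ex vivo.

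Trophectoderm-like cells of the ex vivo library had higher giant cell, unfolded protein response and NRF2 target genes and lower DNA replication and cholesterol genes than those of the in vivo library. Prl3d1, a placental lactogen gene of trophoblast giant cells, had 0 UMIs in vivo and 942 CPM ex vivo, at least 532-fold higher. Hand1, a factor gene that drives giant cell fate, was 10.2-fold higher (27.2 and 276 CPM, 7.59 to 14.0). Fth1, the ferritin heavy chain gene, was 4.31-fold higher (790.4 and 3406 CPM, 4.08 to 4.56). Fos was 7.82-fold lower (277 and 35.5 CPM, 6.57 to 9.34) and Fosb 24.2-fold (43.1 and 1.78 CPM, 12.1 to 54.9, with 42.5% of its in vivo UMIs in 1 cell), while the immediate early list as a whole was inside its range. On mm10, Prl3d1 lies on chromosome 13 (27094190 to 27100258), Hand1 on chromosome 11 (57828705 to 57832818) and Fos on chromosome 12 (85473890 to 85477273).

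The trophoblast differentiation and giant cell list had 9 of 12 measured members higher and 1 lower (median 1.06, range -0.25 to 0.20), and the median was the same with Prl3d1 at its bound. Phlda2, an imprinted gene of the placenta, was 6.85-fold higher (5.42 to 8.77) and the imprinted cell cycle inhibitor Cdkn1c 23.9-fold (13.3 to 48.1). A Prl3d1 UMI was found in 19 of 68 ex vivo cells (27.9%, 17.7 to 40.1%) and in 0 of 27 in vivo cells, which allows a share of up to 11.1% (3 of 27 cells, the limit used for counts of 0). In classes that should lack it, the ex vivo shares were 7.32% of epiblast-like and 1.89% of primitive endoderm-like cells, at median depths of 66864 and 46927 UMIs against 69506 in trophectoderm-like cells. A single cell held 47.1% of the Prl3d1 UMIs, another 64.3% of the ex vivo Cdkn1c UMIs, and 1 in vivo cell held 58.7% of the in vivo Hand1 UMIs. Prl3d1 and Prl3d3 (0 and 394 CPM, at least 222-fold) are near-identical copies, so the split of reads between them is uncertain. Plau, the urokinase gene of invading trophoblast, had 0 and 54.3 CPM (at least 30.7-fold), and its adhesion and invasion list a median of 0.35 (range -0.17 to 0.20) that was -0.05 in thinned cells.

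Other genes with higher ex vivo values included the cytokine gene Il24, 51.5-fold (23.6 to 141), the coagulation inhibitor gene Tfpi, 39.2-fold (19.8 to 91.1), the natriuretic peptide gene Nppb, 10.7-fold (9.02 to 12.7), and Cd47, 21.8-fold (12.9 to 40.1). Jam3 had 1 UMI in vivo and 457 ex vivo, a 153-fold ratio (27.4 to 6074), and Prl5a1 1 and 498, a 167-fold ratio (29.9 to 6617). Prl5a1, Stfa1 and, among the lower genes, Hist1h2ab belong to families with close copies, so their read split is uncertain as well. Rhob, Plac8 and Stfa1 were also among the 12 genes. In thinned cells their log2 ratios were 4.07 against 3.30 for Rhob, 4.02 against 3.05 for Plac8 and 3.77 against 3.04 for Stfa1. Nppb moved from 3.27 to 3.93 as a mean of per-cell CPM. Cdh5 and Pecam1, adhesion genes known from endothelium, were 6.46-fold (4.74 to 9.03) and 24.9-fold (9.63 to 92.1) higher, but 97.6% of the in vivo Cdh5 UMIs came from 1 cell. Their list of 4 measured endothelium markers had a median of 1.48 (range -0.29 to 0.46), or 1.36 with Esam at its bound. At the finer clustering a cluster led by Prl3d1, Nppb and Cdh5 held 2 in vivo and 23 ex vivo cells, and a cluster led by Dppa1 and Gsta1 held 17 of the 27 in vivo and 17 of the 68 ex vivo cells.

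The unfolded protein response list was higher in 10 of 20 members and lower in 0 (median 0.62, range -0.21 to 0.13), with the secreted stress factor gene Manf 2.37-fold (2.10 to 2.69) and Xbp1 2.47-fold (1.75 to 3.56). NRF2 targets were higher in 11 of 22 and lower in 1 (median 0.62, range -0.19 to 0.13), including the autophagy receptor gene Sqstm1, 3.08-fold (2.41 to 3.97), and Gclm, 2.74-fold (2.19 to 3.46). The amino acid and integrated stress response had 12 of 22 members higher and 0 lower (median 0.66, range -0.14 to 0.20, or 0.58 with Slc7a11 and Stc2 at their bounds), such as Trib3, 5.19-fold (2.83 to 10.6), and Nupr1, 4.82-fold (2.95 to 8.41). Of the p53 targets, 6 of 18 were higher (median 0.54, range -0.14 to 0.24), among them Ccng1, 3.12-fold (2.09 to 4.83), and Sesn2, 2.91-fold (1.93 to 4.55). Interferon response genes had 4 of 7 measured members higher (median 0.70, range -0.19 to 0.42), a call that ended in thinned cells.

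Glycolysis genes were lower in 6 of 19 and higher in 2 (median -0.30, range -0.22 to 0.15), with the glucose transporter genes Slc2a3 2.42-fold (1.98 to 2.95) and Slc2a1 1.93-fold lower (1.72 to 2.16). As a mean of per-cell CPM this median was -0.23 and inside its range. Actin genes were lower in 5 of 24 and higher in 1 (median -0.26, range -0.22 to 0.09), including Myh10, 2.08-fold (1.83 to 2.36), and Actg1, 1.60-fold (1.56 to 1.65). In thinned cells the actin median was -0.24, inside a wider random range (-0.30 to 0.12). DNA replication genes were lower in 2 of 32 and higher in 0 (median -0.30, range -0.18 to 0.10), and cholesterol biosynthesis genes lower in 4 of 24 and higher in 1 (median -0.25, range -0.16 to 0.17). The NF-kB inhibitor gene Nfkbia was 3.43-fold lower (2.996 to 3.94), the phosphatase gene Dusp1 2.81-fold (2.29 to 3.45) and Egr1 3.32-fold, with 52.0% of its in vivo UMIs in 1 cell. The immediate early list had 2 of 22 members higher and 4 lower (median 0.09, range -0.15 to 0.21). Further lower genes by the naming rule were Arhgap31, 3.80-fold (3.29 to 4.401), Khdc3, 3.24-fold (2.71 to 3.88), Fbp2, 2.98-fold (2.52 to 3.52), Olfr1459, Hist1h2ab, Camk1d and Shroom3. Camk1d moved from -1.77 to -0.93 in thinned cells and Shroom3 from -1.66 to -1.05 as a mean of per-cell CPM. Trophectoderm markers (-0.03), mural (-0.01) and polar trophectoderm markers (-0.10) and trophoblast stem cell factors (0.10) were inside their ranges.

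**Figure D4:**
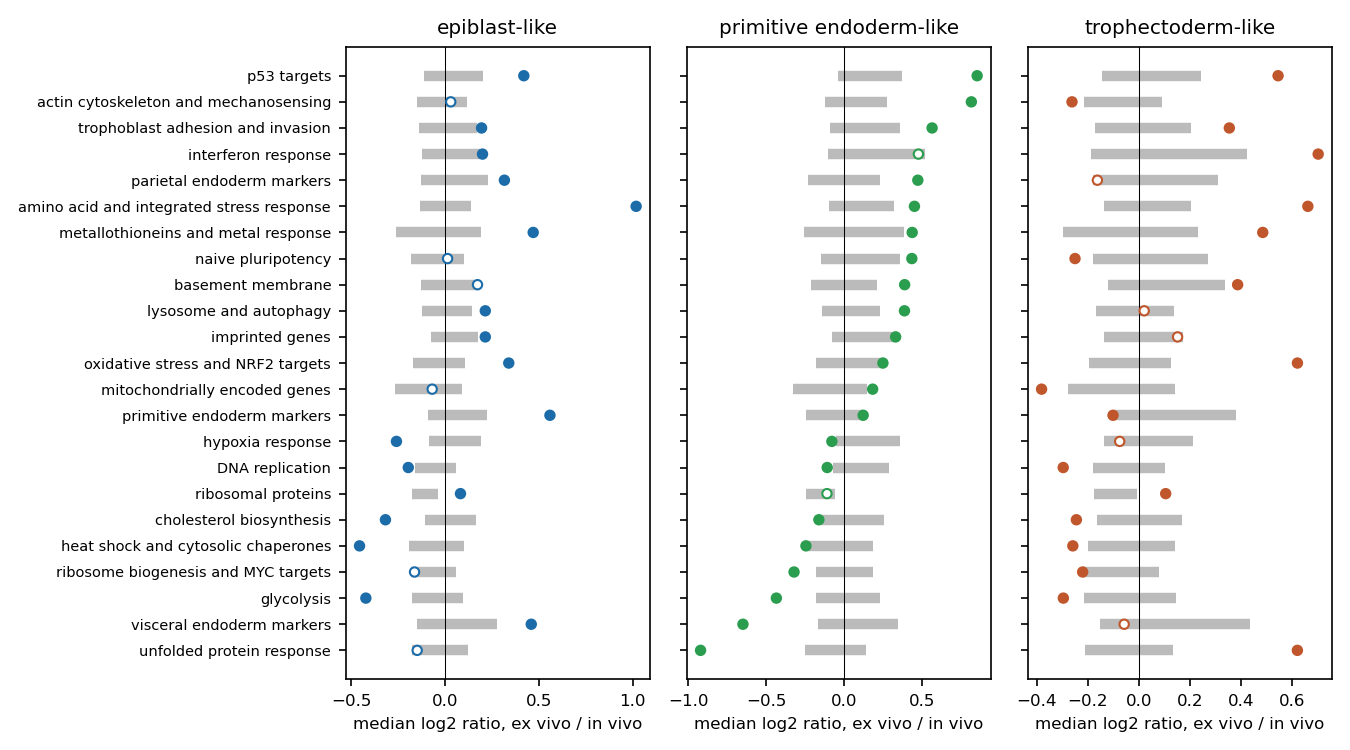
Median log2 ratio (ex vivo over in vivo) in each class for the 23 lists outside the range of random lists in at least 2 classes, where grey bars span the central 95% of 10000 random lists, filled points lie outside it and open points inside. The unfolded protein response list was at -0.92 in primitive endoderm-like and 0.62 in trophectoderm-like cells.

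**Figure D5:**
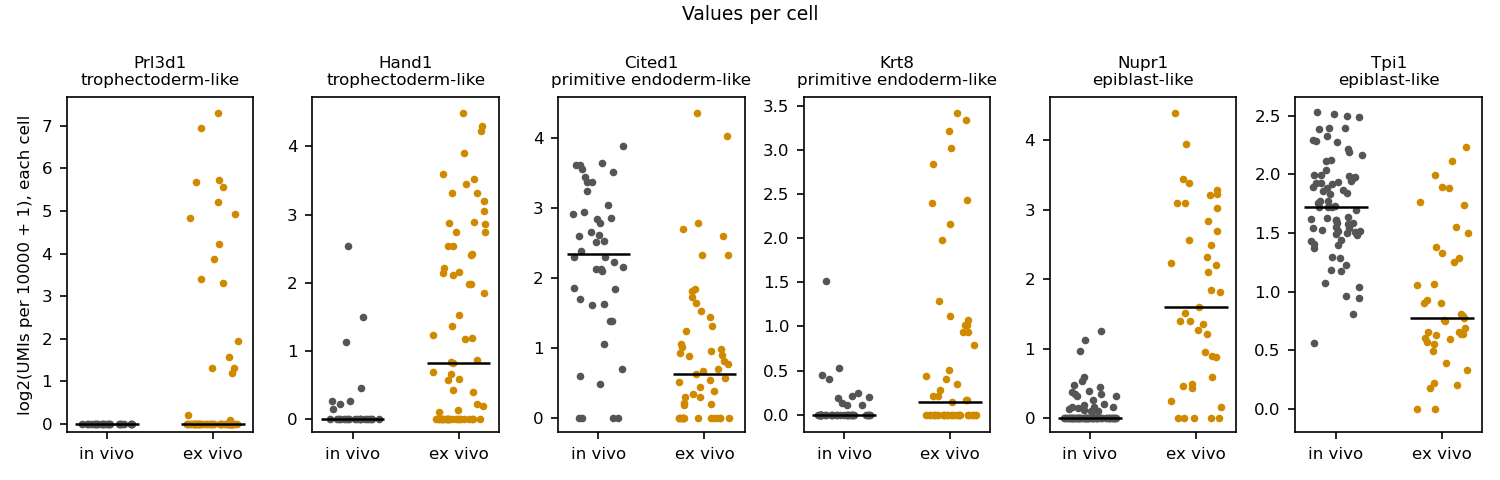
Values per cell as log2 (UMIs per 10000 + 1) in vivo and ex vivo for Prl3d1 and Hand1 in trophectoderm-like, Cited1 and Krt8 in primitive endoderm-like, and Nupr1 and Tpi1 in epiblast-like cells, with a black line at the median. Prl3d1 was seen in 19 of 68 ex vivo and 0 of 27 in vivo cells.

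Xist, the RNA that coats the inactive X chromosome, had 472 CPM in vivo and 572 CPM ex vivo in primitive endoderm-like cells and 205 and 212 CPM in trophectoderm-like cells. Epiblast-like cells had 2.47 and 25.2 CPM, with 52.1% of the ex vivo UMIs in 1 cell. A UMI of a Y-linked gene (Ddx3y, Eif2s3y, Uty or Kdm5d) was found in 71.4% (63.4 to 78.6%) of the in vivo and 57.4% (49.4 to 65.1%) of the ex vivo cells. Xist UMIs were found in 38.8% (30.9 to 47.2%) and 50.6% (42.7 to 58.6%), and 24.5% and 23.5% of cells held both kinds, at median depths of 81315 and 62864 UMIs. Whether cells with both kinds were doublets or held RNA of other cells was not tested. In epiblast-like cells the Y-linked share was 80.3% (69.5 to 88.5%) in vivo and 53.7% (37.4 to 69.3%) ex vivo. A different mix of sexes in this class therefore stays open. In cells thinned to 13000 UMIs the Y-linked shares were 48.1% and 40.0%.

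Markers of cells outside the embryo were summed over all kept cells, and 0 clusters took such a name. Uterine epithelium markers summed to 121 CPM (115 to 128) in vivo and 152 CPM (145 to 160) ex vivo, of which Wfdc2 made up 86.7% and 79.2%. In vivo, Wfdc2 was at 125 CPM (117 to 133) in epiblast-like, 43.9 CPM (36.7 to 52.1) in primitive endoderm-like and 132 CPM (115 to 151) in trophectoderm-like cells. Endothelium markers summed to 146 CPM (139 to 153) in vivo and 236 CPM (227 to 246) ex vivo, led by Egfl7 in vivo and by Cdh5 ex vivo. Stroma and decidua markers were at 14.0 and 16.6 CPM, and blood and immune markers at 37.0 and 70.8 CPM. Within trophectoderm-like cells S100a9, known from neutrophils, had 80.3 CPM in vivo and 58.3 ex vivo, and S100a8 41.3 and 47.6 CPM. In the other classes each had at most 1 UMI per library. Ex vivo Cdh5 had 808 UMIs in trophectoderm-like, 1 in epiblast-like and 3 in primitive endoderm-like cells. Sums over all kept cells led by these genes therefore also follow the share of trophectoderm-like cells. Erythroid markers were at 0.519 and 2.26 CPM.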

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

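The tests on deeper cells, endothelial genes, the Prl3d copies, the mix of picked cells, trophectoderm RNA, free RNA and dissociation were chosen after the result was seen. With 1 library per group, differences between classes could not be tested, and a median on opposite sides of its random ranges in 2 classes is what drew attention to a list. The unfolded protein response differed by 1.54 on the log2 scale, with a median of 0.62 in trophectoderm-like and -0.92 in primitive endoderm-like cells. Visceral endoderm markers differed by 1.11 (0.46 in epiblast-like and -0.65 in primitive endoderm-like cells), and actin genes by 1.08 (0.81 in primitive endoderm-like and -0.26 in trophectoderm-like cells). Naive pluripotency genes differed by 0.68 (0.43 in primitive endoderm-like and -0.25 in trophectoderm-like cells), primitive endoderm markers by 0.66 (0.56 in epiblast-like and -0.10 in trophectoderm-like cells), and mitochondrially encoded genes by 0.56 (0.18 in primitive endoderm-like and -0.38 in trophectoderm-like cells). None of these differences was tested. With marker-score classes, which held 38 rather than 41 ex vivo epiblast-like cells, the epiblast-like medians were 0.088 for visceral and 0.12 for primitive endoderm markers. The epiblast-like side of these differences therefore depends largely on which cells are in the class. At least 1 alternative ended a call on the epiblast-like side for visceral endoderm markers, on the trophectoderm-like side for actin genes and on both sides for the naive pluripotency, primitive endoderm marker and mitochondrial lists, whereas both sides held for the unfolded protein response. The feature gtdTomato, a red fluorescent reporter that the labels do not mention for these embryos, had 35 UMIs in the kept in vivo cells and 51 in the kept ex vivo cells, above the limit a count of 0 allows, and its origin was not tested.

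In ex vivo trophectoderm-like cells, giant cell genes such as Prl3d1, Hand1 and Phlda2 were higher, together with Cdh5 and Pecam1. Endothelial cells or their RNA are argued against, since the highest of Kdr, Cldn5, Emcn and Plvap reached 0.396 CPM while Cdh5 had 160.1 and Pecam1 58.9 CPM. Reads split among the Prl3d copies do not explain the list, because 8 of the 11 other measured members were at least 1.5-fold higher. A different mix of picked trophectoderm cells stays open: the in vivo count of 0 allows up to 11.1% of cells with a Prl3d1 UMI (3 of 27) against 27.9% ex vivo (17.7 to 40.1%), but hand picking could have favoured a region of the trophectoderm in 1 library. Culture against development in the uterus, a possible difference in stage and the library itself cannot be told apart as sources, and none was tested.

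In ex vivo primitive endoderm-like cells, visceral endoderm markers were lower and keratin and actin genes higher. Trophectoderm RNA or doublets would have brought Elf5, Tfap2c, Gata3 and Krt7 along with Krt8, yet these reached 5.01% (2.97 to 7.92%) of what the Krt8 gain needs. Shallow or damaged cells are argued against by the deeper cells, where the visceral endoderm median was -0.76 (range -0.18 to 0.33, 31 in vivo and 34 ex vivo cells). More nuclear RNA is a candidate explanation because Malat1 had 1935 CPM in vivo and 5208 CPM ex vivo. The visceral endoderm markers, however, stayed at percentile 0 among random lists matched on expression and gene span. Other lists of this class, such as actin and unfolded protein response genes, were not compared in this way, so nuclear RNA stays open for them. Immediate early genes also lay above their range in this class (11 of 18 higher, median 0.74, range -0.04 to 0.38). A response to dissociation was not tested for this pattern and stays open. A difference of culture from development in vivo may underlie the pattern as an untested hypothesis. Culture cannot be told apart from a difference in stage or a batch difference between the libraries.

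Genes of the amino acid and integrated stress response, Nupr1 among them, were higher ex vivo in all 3 classes. Free RNA in the ex vivo suspension would add a like amount to every class. The summed gains were 1554 CPM in epiblast-like, 626 in primitive endoderm-like and 423 in trophectoderm-like cells, a ratio of 3.68 between the largest and the smallest. Free RNA alone is therefore argued against for the epiblast-like gain. The gains of the other classes lie closer together, so free RNA stays open for them. The immediate early genes, taken as a sign of a response to dissociation, were inside their range in epiblast-like and trophectoderm-like cells (percentiles 6.73 and 76.2). They lay above it in primitive endoderm-like cells. Stress response genes were thus higher in 2 classes without such a shift. Whether the stress response genes need the immediate early genes to rise with them was not tested. A difference between the libraries in the response to dissociation therefore stays open. Shallow or damaged cells are argued against by the deeper cells, in which the list stayed above its range in 3 classes (1.16, 0.48 and 0.65). A part played by depth stays open in primitive endoderm-like cells, where the median in thinned cells was 0.30 and inside its range. Whether culture, stage or library preparation is the source also stays open. With the same 2 libraries these cannot be told apart, and none was tested.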

How the results depend on the processing

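The setting of deeper cells only was chosen after the data were seen, and the other 13 settings before. Lists outside their random range kept their side in 899 recalculations, moved inside it in 75 and in 6 took the opposite direction relative to their random lists. In all 14 settings 10 lists kept their side in epiblast-like (E), 17 in primitive endoderm-like (P) and 10 in trophectoderm-like (T) cells. They include glycolysis, cholesterol and DNA replication in E and P, cholesterol, DNA replication, giant cells and the unfolded protein response in T, and visceral endoderm markers and the unfolded protein response in P. Named genes kept their direction in every setting that recomputes them (725 values inside the counting interval, 139 outside it). Of the lists inside their range, 882 values stayed there, 56 left it on their own side and 1 on the other. Class shares stayed within their intervals in 33 recalculations and left them in 3. Resolutions 0.25 and 1.0 gave the same classes and so the same values, which are among those counted as kept but tested nothing. The removal of called doublets changed no side, but it took out only 2 in vivo cells and 1 ex vivo cell. It cannot show the effect of doublets that were not called. No paired analysis was possible because embryos were pooled and no barcode carries its embryo. Depth limits what can be seen for genes with few UMIs and for shares of cells with a UMI.

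Values that changed side or left their interval were as follows, as list medians unless stated, and the cause was not tested unless given. With the looser filter, 34 in vivo and 40 ex vivo cells had no class name and count in the total of each share. The shares that left their intervals were E with 39.7% in vivo and 18.1% ex vivo, and T 31.9% ex vivo. Uterine epithelium markers were at 167 CPM ex vivo. In E, primitive endoderm (0.11) and visceral endoderm markers (0.090) moved inside their ranges and parietal endoderm markers (0.0086) to the opposite direction. In P, formative genes (0.023), growth factors (0.37) and primitive endoderm markers (0.076) moved inside. With the stricter filter, T lost the call for mesenchymal transition (0.39), mitochondrially encoded (-0.21) and ribosome biogenesis genes (-0.20).

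With marker-score classes, E had primitive endoderm (0.12), visceral endoderm (0.088) and, reversed, parietal endoderm markers (0.0019). P had formative genes (0.00047), heat shock genes (-0.23) and primitive endoderm markers (0.078) inside, and T ribosome biogenesis (-0.22) and primitive endoderm markers (-0.069). Scaling by the median of ratios ended the calls for imprinted genes in P (0.22) and mesenchymal transition in T (0.43). Totals without mitochondrial and ribosomal genes did so for imprinted genes (0.34) and primitive endoderm markers (0.11) in P.

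As means of per-cell CPM, E lost oxidative phosphorylation (-0.042), interferon (0.19) and imprinted genes (0.23). P lost naive pluripotency (0.38), hypoxia (0.11), heat shock (-0.17) and imprinted genes (0.32). T lost adhesion (0.14), basement membrane (0.34), glycolysis (-0.23), heat shock (-0.23), ribosome biogenesis (-0.24), epiblast (-0.23) and primitive endoderm markers (-0.094). A pseudocount of 1 CPM ended calls for heat shock (-0.25) and primitive endoderm markers (0.12) in P and basement membrane in T (0.65).

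Thinning measures fewer members and gave Y-linked shares of 48.1% in vivo and 40.0% ex vivo and an Xist share of 28.1% in vivo. It ended calls in E for p53 targets (0.26) and parietal endoderm markers (0.35). In P it did so for adhesion (0.24), hypoxia (0.080), the integrated stress response (0.30), heat shock (-0.25), imprinted genes (0.30) and growth factors (0.28). In T the same held for naive pluripotency (-0.28), adhesion (-0.047), basement membrane (0.46), mesenchymal transition (0.46), heat shock (-0.24), ribosome biogenesis (-0.25), interferon (0.52), actin (-0.24) and epiblast markers (-0.24), and primitive endoderm markers reversed (0.46).

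Requiring at least 100 UMIs leaves fewer members. It ended calls for interferon in E (0.18), adhesion (0.37), visceral endoderm transport (-0.13), hypoxia (0.061) and heat shock (-0.26) in P, and naive pluripotency (-0.27) and heat shock (-0.24) in T, where basement membrane (-0.28) and mesenchymal transition (-0.25) reversed. Accepting members from 1 UMI adds genes near 0. It ended calls for adhesion in E (0.11), and in P for formative (0.026), mitochondrially encoded (0.18) and NRF2 genes (0.23) and primitive endoderm (0.12) and trophectoderm markers (0.10). In T it did so for naive pluripotency (-0.051), mesenchymal transition (0.083), interferon (0.10), epiblast (0.027) and primitive endoderm markers (0.013), and basement membrane reversed (0.056). Deeper cells only ended calls for mitochondrially encoded genes (0.11) and primitive endoderm markers (0.076) in P and for mitochondrially encoded (-0.19) and ribosome biogenesis genes (-0.17) in T.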

Other observations

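The test in this part was chosen after the result was seen. Barcodes left out by the filter had medians of 1138 UMIs in vivo and 1356 ex vivo, and gtdTomato had 0 UMIs in them. The exact Poisson upper limits there were 13.6 CPM in vivo and 22.3 CPM ex vivo, above the 3.03 and 4.80 CPM of kept cells. These counts of 0 therefore cannot show whether gtdTomato was lower in the barcodes left out. Among kept cells a gtdTomato UMI was found in 28 of 147 in vivo (19.05%) and 35 of 162 ex vivo cells (21.6%), with at most 2 and 4 in 1 cell.

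Epiblast-like cells formed 2 clusters present in both libraries, with 41 in vivo and 24 ex vivo cells in cluster 1 (led by Trh, Uchl1 and Gdf3) and 35 and 17 in cluster 3 (led by Enox1, Bnc2 and Nfib). The 100 genes highest in cluster 3 over cluster 1 had a median span of 175 kb, against 20.01 to 36.2 kb in random lists matched on expression. Since these genes were chosen by that ratio, the longest 10% of the measured genes not used for clustering were compared within each library. Their median log2 ratio of cluster 3 over cluster 1 was 0.40 in vivo (random lists 0.04 to 0.09) and 0.37 ex vivo (0.06 to 0.13). The nuclear RNA Malat1 was at 2685 CPM in cluster 1 and 3256 CPM in cluster 3 in vivo, but at 3808 and 3962 CPM ex vivo, a small difference. A larger share of unspliced or nuclear RNA in cluster 3 may underlie this, a hypothesis that spliced and unspliced read counts would be needed to test.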
